A study of Mus musculus with 12 samples.

How the data were processed

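Total RNA of sorted T cells was extracted with Trizol and RNeasy columns, checked for quality on a Bioanalyzer, and 250 ng per sample was turned into biotin-labelled cDNA with the GeneChip WT Plus kit, per the labels' protocols. The deposited values are log2 expression values per transcript cluster and array, made with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, gives all arrays the same distribution and summarises the probes of a cluster, so a change in the total RNA per cell would not show in these values. The versions of both tools, the genome build and the annotation are not given in the sources used here. The table held 34365 clusters for 12 arrays with no column of other samples, and the medians of the arrays lay between 5.23 and 5.33. Scanner files were not used here, so the background correction and summary were not repeated. No batch, scan date or slide is given in the labels, and none could be tested.

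Clusters were named through the platform annotation. Of the clusters 23521 had 1 gene symbol, 1814 had several and 9030 had none listed. Clusters with several or no symbols stayed out of the comparisons and were fitted apart. For 1082 genes with more than 1 cluster the brightest cluster over all arrays stood for the gene, which left 22180 genes, none removed for a low level. Genes with near-identical copies, such as granzymes, killer lectin-like receptors and Oas, Ifit and Ly6c genes, are uncertain because probes can read more than 1 copy.

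All 12 arrays entered one linear model with 4 group means, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend and not robust. It had 8 residual degrees of freedom, and eBayes added a prior of 4.56 degrees of freedom with a prior SD of 0.142. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The 5 contrasts were Foxp3-positive against control in CD8 and in CD4 cells, the interaction of these effects, and CD8 against CD4 in Foxp3-positive and in control cells. Mean levels, standard errors and fold changes come from the same model.

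Expression of 24 lists of genes was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. The lists had 477 entries of 429 different genes, of which 434 entries of 387 genes were measured and 43 genes stood in more than 1 list. They covered the regulatory T cell signature, responses to TGF-β and retinoic acid, T cell effector, helper, memory, receptor and activation genes, the cell cycle, metabolism, stress and interferon responses, lineages, and markers of dendritic, B, macrophage, NK and γδ, and red cells and platelets. Camera was repeated with the correlation estimated from the data, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, gave 16 lists in CD8 cells, 16 in CD4 cells, 14 for the interaction, 11 in Foxp3-positive cells and 15 in controls. With an estimated correlation the regulatory signature and TGF-β response passed in CD8 cells, and the TGF-β response and helper cytokines in CD4 cells. For the interaction and for the controls 5 lists each passed, the regulatory signature, TGF-β response, helper cytokines, interferon-stimulated genes and CD4 lineage, and for Foxp3-positive cells the CD8 lineage.

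The genes named in the text follow a rule. It takes Foxp3, Cd4, Cd8a and Cd8b1, then the 8 largest rises and 8 largest falls of each Foxp3-positive against control comparison and 6 of each for the other comparisons. Those genes needed an adjusted p under 0.05, a mean in the higher group of at least 5.60 (the median of all genes) and, outside the interaction, no overlap between the arrays of the groups. Predicted genes, clone names and small RNAs were passed over. From each list the rule takes the 3 members with the largest change past the threshold in CD8 or CD4 cells, and the brightest member that passed in neither. Other list members are named in many places where a count was 5 or fewer, but not for every such count, and lie outside the rule. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. Lists of interferon-γ targets, type 2 helper genes, abundant dendritic cell genes and gene families were written after the first results were seen. Tests that use these lists were therefore not fixed beforehand.

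The model and camera were tested on simulated data with the levels and spreads of the real 22180 genes and 200 genes changed by known amounts. For changes of 0.5, 1 and 2 on the log2 scale, 34.3%, 88.1% and 98.5% were recovered in the CD8 comparison and 31.3%, 91% and 100% in the CD4 comparison. For the interaction these shares were 6%, 68.7% and 95.5%, for Foxp3-positive cells 44.8%, 89.6% and 98.5%, and for controls 44.8%, 83.6% and 98.5%. False calls made up 3.9, 5.1, 2.6, 3.7 and 3.2% of the calls in that order. The cell cycle list shifted by 0.5 was found in all 5 simulations, and 2 other lists were called in the CD8 simulation and 0 in the others. Simulated noise was independent between genes, but the real cell cycle list had an estimated correlation of 0.562. List counts thus do not cover correlated lists.

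The alternatives were a second quantile normalization, centring each array on its median, leaving out the lowest 33.3% of genes by mean level, eBayes with trend and robust, array weights, the mean over the clusters of a gene, the replicate letter as a block, and a model of only the groups compared. Stricter thresholds of 0.01 and of a 2-fold change, estimated correlations in camera, and leaving out each of the 12 arrays in turn were also tried.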

Results

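RNA was measured on 12 Affymetrix GeneChip arrays from alloreactive mouse T cells, that is, T cells stimulated by dendritic cells of another mouse strain. The T cells came from C57BL/6 animals in which green fluorescent protein (GFP) reports Foxp3, the transcription factor of regulatory T cells. CD4 or CD8 cells (200000 per well) were cultured with 20000 BALB/c dendritic cells sorted by CD11c. Control wells received IL-2 at 5 ng/mL alone, and their GFP-negative T cells were collected. The other wells received the same IL-2 together with TGF-β at 5 ng/mL and retinoic acid at 40 nM, and their GFP-positive T cells were collected. CD8 cells were cultured for 4 days and CD4 cells for 5 days. These steps gave 4 groups of 3 arrays, replicates A to C, called here CD8 control, CD8 Foxp3-positive, CD4 control and CD4 Foxp3-positive. Values are log2 expression levels given as mean ± SD over the 3 arrays of a group, and log2 fold changes are given with the standard error of the limma model and its adjusted p. No background level was available, so folds against means near or below 5.60, the median of all genes' means, as for Il13, are ratios of array signal and not of RNA amount. Within each cell type the cytokine treatment and the Foxp3 sort changed together, so a difference belongs to both. Cells were pooled before staining, and the labels do not say that the replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical, and 3 arrays per group limit the precision.

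The arrays grouped by cell type and treatment. Across the 22180 genes, which are not independent replicates, arrays of one group correlated at r = 0.992 to 0.995, and arrays of different groups at 0.962 to 0.991. The Foxp3-positive groups of the CD8 and CD4 lineages were the closest pair of groups (median r = 0.989), while the CD8 and CD4 controls had a median of 0.977. The first principal component held 47.2% of the variance and separated the Foxp3-positive arrays (28.62 to 38.57) from the controls (-41.81 to -20.35). The second held 22.7% and placed the CD8 controls at 33.98 to 36.79 and the CD4 controls at -28.18 to -25.6. On that component the Foxp3-positive arrays lay between the controls, at 1.49 to 4.19 for CD8 and at -11.95 to -10.11 for CD4.

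**Figure D1:**
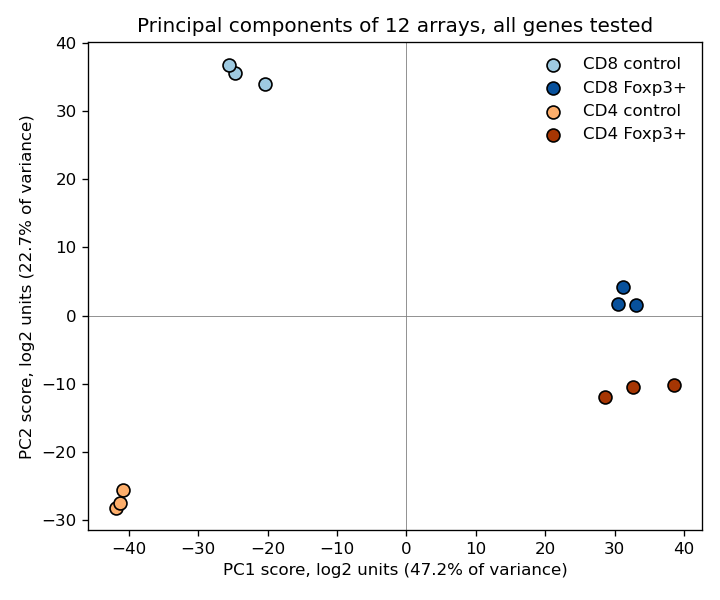
Scores of the 12 arrays on the first principal components of 22180 genes, in units of the component score, with 1 point per array and colours for the 4 groups. The Foxp3-positive arrays sit at 28.62 to 38.57 on the first component, and the controls part by cell type on the second.

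The genes that check the labels followed them. Foxp3 stood at 5.66 ± 0.59 in CD8 controls and 12.48 ± 0.05 in CD8 Foxp3-positive cells, a 113-fold rise (log2 fold change 6.83 ± 0.23, adjusted p = 8.26e-10), which follows from the sort on the reporter. In CD4 cells it rose 103-fold, from 5.76 ± 0.29 to 12.44 ± 0.05 (log2 fold change 6.68 ± 0.23, adjusted p = 5.83e-10). Cd4, the helper T cell coreceptor, was at 12.31 ± 0.12 in CD4 controls and 11.92 ± 0.11 in CD4 Foxp3-positive cells, against 5.36 ± 0.58 and 5.18 ± 0.25 in the CD8 groups. The CD8 coreceptor chain Cd8b1 was at 11.86 ± 0.04 and 11.97 ± 0.03 in CD8 controls and CD8 Foxp3-positive cells. In CD4 cells it was at 7.72 ± 0.26 in controls and fell 2.93-fold to 6.17 ± 0.24 (log2 fold change -1.55 ± 0.14, adjusted p = 2.81e-06). Cd8a was at 11.79 ± 0.08 and 12.54 ± 0.03 in the CD8 groups and at 6.51 ± 0.72 and 7.54 ± 0.55 in the CD4 groups. Its rise in CD4 cells (log2 fold change 1.03 ± 0.30, adjusted p = 0.0273) lost its call without CD4 control replicate C or CD4 Foxp3-positive replicate C (adjusted p from 0.0967 to 0.107, log2 fold change 0.64 without CD4 control replicate C against 1.03).

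Markers of other cell types were set against 5.60, the median of all genes' mean levels. Of 19 markers of dendritic cells, which were present in the cultures, 10 lay above it, and their median was 5.97 in CD8 controls, 5.76 in CD8 Foxp3-positive, 5.69 in CD4 control and 5.63 in CD4 Foxp3-positive cells. Macrophage and monocyte markers (14 measured) had medians of 5.03, 5.5, 5.22 and 5.38 in the same order. The medians of 12 B cell markers ranged from 4.87 to 4.97, those of 7 NK and γδ T cell markers from 4.72 to 5.12, and those of 6 red cell and platelet markers from 4.75 to 4.91. Single members stood high in all 4 groups. The class II gene H2-Ab1 was at 9.49, 9.45, 10.00 and 8.95 and the protease inhibitor gene Cst3 at 8.17, 8.54, 8.24 and 8.26, both chosen after their values were seen. Cd209a, a dendritic cell lectin, was at 9.40, 9.47, 9.34 and 9.23. Cathepsin B (Ctsb) was at 11.06 to 11.52, and the immunoglobulin heavy chain Ighm at 10.96 to 13.15. Without a background level, a value above or below 5.60 does not show whether a cell type was present.

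**Figure D2:**
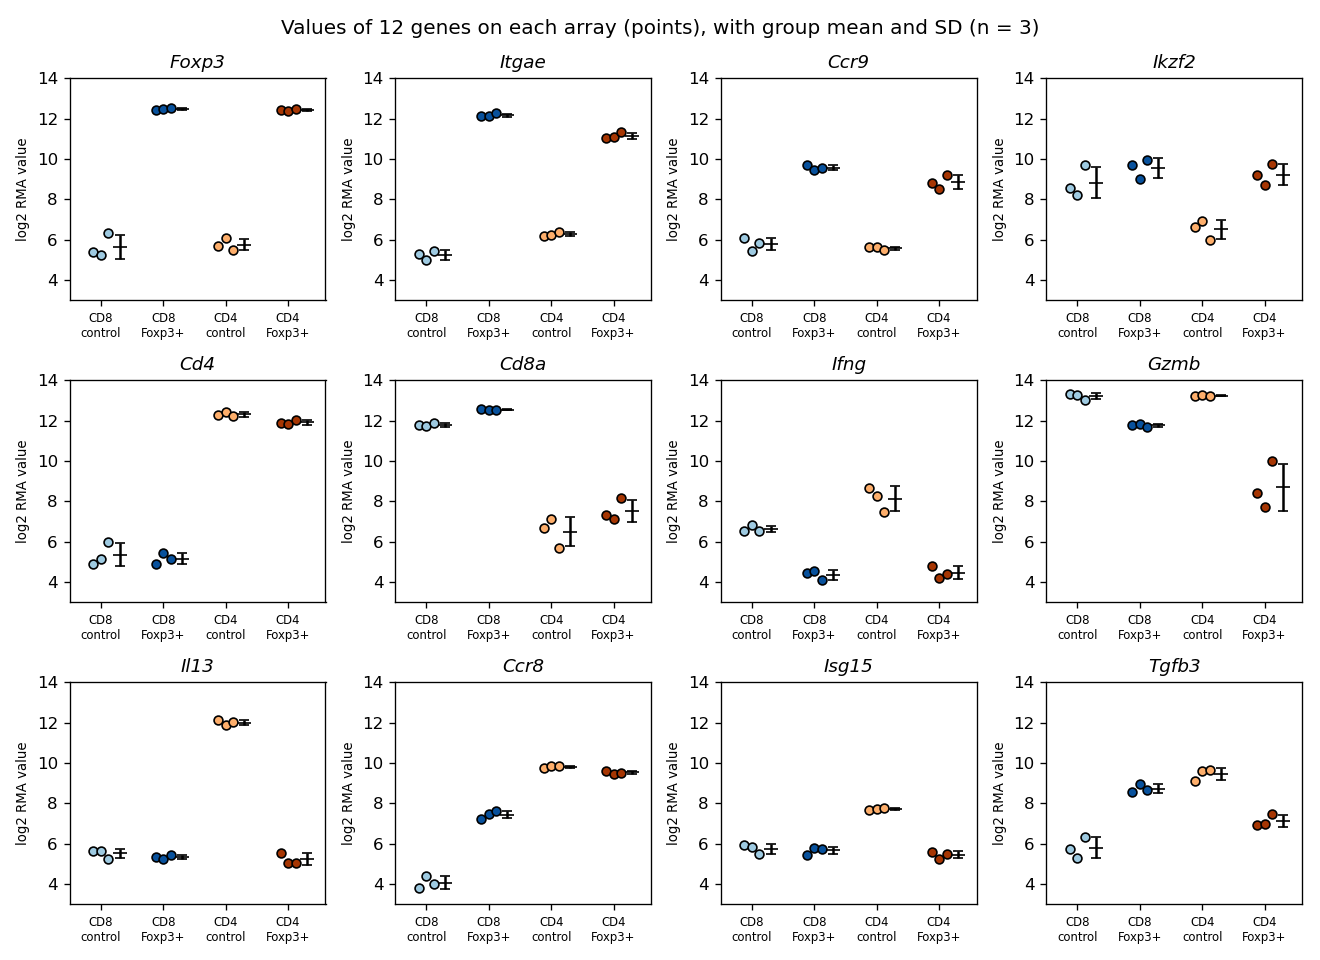
Log2 expression of 12 genes on each array (points), with the group mean and SD of 3 arrays, for the CD8 control, CD8 Foxp3-positive, CD4 control and CD4 Foxp3-positive groups. Foxp3, Itgae and Ccr9 are high in both Foxp3-positive groups, while Il13 reaches 12.01 in the CD4 controls and lies between 5.24 and 5.53 in the other groups. Ikzf2, Ifng and Isg15 lie outside the rule for named genes and were chosen after their values were seen.

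The first comparison asks how CD8 T cells that had become Foxp3-positive with TGF-β and retinoic acid differed from CD8 T cells stimulated with IL-2 alone. Itgae, the integrin chain CD103 that binds E-cadherin on epithelium, rose 122-fold from 5.25 ± 0.24 to 12.18 ± 0.07 (log2 fold change 6.93 ± 0.12, adjusted p = 3.83e-12). Ldlrad4, an inhibitor of Smad signalling that TGF-β induces, rose 42.3-fold (log2 fold change 5.40 ± 0.13, adjusted p = 4.03e-11). Xcl1, a chemokine that attracts cross-presenting dendritic cells, rose 34.2-fold (log2 fold change 5.10 ± 0.17, adjusted p = 8.26e-10), and Tph1, the first enzyme of serotonin synthesis, 36.8-fold (log2 fold change 5.20 ± 0.23, adjusted p = 8.36e-09). Ly6c2, which encodes the surface antigen Ly6C of effector and memory cells, fell 90.8-fold from 12.48 ± 0.26 to 5.98 ± 0.77 (log2 fold change -6.51 ± 0.36, adjusted p = 6.2e-08). Ccr2, a receptor for inflammatory chemokines, fell 14.7-fold (log2 fold change -3.88 ± 0.22, adjusted p = 6.25e-08).

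In all, 4430 of 22180 genes passed limma's adjusted threshold of 0.05, 2083 higher and 2347 lower in Foxp3-positive CD8 cells. A change of at least 2-fold was seen for 511 of the higher and 292 of the lower genes. Among the other large rises were Apol9b, of the apolipoprotein L family, at 6.15 ± 0.38, the adhesion gene Hepacam2 at 5.33 ± 0.18 and the immunoglobulin variable gene Igh-VS107 at 5.26 ± 0.14. Probes of Apol9b can also read its near copy Apol9a, and those of Ly6c2 its near copy Ly6c1, so both genes are uncertain. The large falls also held the IL-12 receptor chain Il12rb2 (-3.81 ± 0.39), the semaphorin Sema4a (-4.13 ± 0.13) and Galnt3, an enzyme that starts O-linked glycans (-3.59 ± 0.13). Ier3, an immediate early gene, Adam8, a surface protease, and Anxa2, a membrane-binding annexin, fell by 3.50, 3.41 and 3.22 on the log2 scale. The arrays of both groups did not overlap for 33.5% of all genes, where chance alone gives 10% for 3 arrays against 3. The naming rule asked for no overlap in part of the named genes, so no share is given for them. Among those that passed, the arrays of Il24 overlapped. Its call was lost with any single array left out except replicate C of either CD8 group. Adjusted p ran from 0.0563 to 0.192, and the log2 fold change was -0.47 without CD8 control replicate B against -0.77.

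Genes of the regulatory T cell signature rose as a list in CD8 cells. Of 28 measured members, 19 rose and 1 fell (21 and 2 adjusted over the list alone), with camera adjusted p = 7.53e-17, and adjusted p = 0.00169 with an estimated correlation. Besides Foxp3 and Itgae, the adenosine-producing enzyme Nt5e (CD73) rose 15.1-fold (log2 fold change 3.92 ± 0.17, adjusted p = 8.36e-09). The member that fell was Tnfrsf9, the costimulatory receptor 4-1BB (-0.95 ± 0.18, adjusted p = 0.00205), and Penk, which encodes enkephalin, did not pass (-0.18 ± 0.15, adjusted p = 0.507). Tnfrsf9 and other list members given only because 5 or fewer members moved lie outside the naming rule and were chosen after their values were seen.

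Of 24 TGF-β response genes 13 rose and 1, Id2, fell (14 and 1 adjusted over the list alone), with camera adjusted p = 7.79e-12, and adjusted p = 0.00118 with an estimated correlation. The chemokine receptor Ccr8 rose 10.4-fold (log2 fold change 3.37 ± 0.14, adjusted p = 7.28e-09) and the cytokine Tgfb3 by 2.94 ± 0.24, while the matrix protein Tgfbi did not pass (0.25 ± 0.15, adjusted p = 0.324). Of 18 retinoic acid response and gut homing genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 3.39e-08, and adjusted p = 0.111 with an estimated correlation. Ccr9, the receptor that guides T cells to the small intestine, rose 13.8-fold (log2 fold change 3.78 ± 0.18, adjusted p = 1.37e-08). P2rx7, an ATP-gated channel, and Dhrs3, a retinaldehyde reductase, rose 12-fold and 7.87-fold, and the retinoic acid receptor Rara did not pass (0.29 ± 0.10, adjusted p = 0.0566).

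Of 27 cytotoxic effector genes 6 rose and 12 fell (7 and 14 adjusted over the list alone), with camera adjusted p = 0.0378, and adjusted p = 0.51 with an estimated correlation. Granzyme genes Gzmb and Gzmd fell by 1.44 ± 0.39 and 3.00 ± 0.63 on the log2 scale. Both are uncertain because their array probes can read near-identical granzymes, and the Gzmb call was lost without CD8 control replicate A, CD8 control replicate B or CD8 Foxp3-positive replicate C (adjusted p from 0.054 to 0.0619). Gzma (-0.70 ± 0.37, adjusted p = 0.235) and Gzmm (-0.42 ± 0.17, adjusted p = 0.118) did not pass. Eomes, a transcription factor of cytotoxic cells, fell 9.11-fold (log2 fold change -3.19 ± 0.22, adjusted p = 5.22e-07). It belongs to the CD8 lineage list, in which 3 of 10 members rose, Itgae, Xcl1 and the receptor Klrd1, and 2 fell, Eomes and Gzmk (4 and 2 adjusted over the list alone). That list did not pass (camera adjusted p = 0.09, and adjusted p = 0.521 with an estimated correlation). Of 15 helper lineage factors 7 rose and 3 fell, Il12rb2, Tbx21 and Il18r1 (7 and 3 adjusted over the list alone), with camera adjusted p = 0.0243, and adjusted p = 0.169 with an estimated correlation. The transcription factors Maf and Ahr rose 11.6-fold and 8.42-fold, and Stat4 did not pass (-0.04 ± 0.12, adjusted p = 0.892).

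Lists of proliferation and biosynthesis genes fell in Foxp3-positive CD8 cells with the preset correlation, and none of these calls held with an estimated one. Of 29 cell cycle genes 27 fell and none rose (0 and 29 adjusted over the list alone), by a median of -0.56, with camera adjusted p = 1.08e-14, and adjusted p = 0.17 with an estimated correlation. The replication licensing genes Cdc6 and Cdt1 changed by -0.89 ± 0.15 and -0.89 ± 0.10, and Tyms did not pass (-0.31 ± 0.12, adjusted p = 0.104). Cholesterol synthesis genes fell in 17 of 18 cases and rose in none (0 and 17 adjusted over the list alone), with camera adjusted p = 1.56e-12, and adjusted p = 0.111 with an estimated correlation. Hmgcs1, an early enzyme of the pathway, fell 3.15-fold (log2 fold change -1.65 ± 0.17, adjusted p = 1.38e-05), and Ebp was unaltered within error (0.07 ± 0.10, adjusted p = 0.716). In the list of unfolded protein and amino acid stress, 2 of 19 genes rose, Sesn2 and Xbp1, and 10 fell (3 and 10 adjusted over the list alone), with camera adjusted p = 3.95e-05, and adjusted p = 0.315 with an estimated correlation. Asns, which makes asparagine, fell 5.93-fold (log2 fold change -2.57 ± 0.11, adjusted p = 8.36e-09), and the amino acid transporter Slc7a5 3.69-fold. Glycolysis genes fell in 4 of 18 cases, Slc2a3, Pfkp, Ldha and Pgk1, and rose in none (0 and 4 adjusted over the list alone), with camera adjusted p = 0.00696, and adjusted p = 0.51 with an estimated correlation. The call for Slc2a3, a glucose transporter (-0.95 ± 0.26, adjusted p = 0.0187), was lost without CD8 control replicate A, CD8 Foxp3-positive replicate B or CD8 Foxp3-positive replicate C (adjusted p from 0.0624 to 0.0812).

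Surface receptor genes moved both ways. Of 19 inhibitory receptor and exhaustion genes 12 rose and 2 fell, Havcr2 and Pdcd1 (12 and 3 adjusted over the list alone), with camera adjusted p = 0.000174, and adjusted p = 0.137 with an estimated correlation. Havcr2 (TIM-3) fell 8.22-fold (log2 fold change -3.04 ± 0.12, adjusted p = 5.03e-09), and Tox, a transcription factor of exhausted T cells, rose 4.16-fold (log2 fold change 2.06 ± 0.17, adjusted p = 1.98e-06). Cd5 did not pass (0.21 ± 0.11, adjusted p = 0.233). Of 25 chemokine receptors and integrins 10 rose and 5 fell, Ccr2, Itgal, Cxcr6, Itgb1 and Cxcr4 (12 and 6 adjusted over the list alone), with camera adjusted p = 0.0238, and adjusted p = 0.294 with an estimated correlation. The selectin ligand Selplg did not pass (0.22 ± 0.08, adjusted p = 0.0715). In the CD4 lineage list 5 of 10 members rose, Cxcr5, Izumo1r, Il4, Icos and Tnfrsf4, and 1, Zbtb7b, fell (5 and 1 adjusted over the list alone), with camera adjusted p = 0.021, and adjusted p = 0.137 with an estimated correlation. Cxcr5, the follicle homing receptor, rose 8.24-fold, and Izumo1r, the folate receptor FR4, 7.75-fold. The rise of Il4 (0.59 ± 0.15, adjusted p = 0.0125) was lost without CD8 control replicate A or CD8 Foxp3-positive replicate B (adjusted p from 0.0593 to 0.0607).

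The remaining lists did not pass in CD8 cells. Helper cytokine genes rose in 5 of 17 cases and fell in 1, Ifng (camera adjusted p = 0.363), with Lta up 2.62-fold. Naive and memory genes rose in 5 of 14 and fell in 6 (0.969), with the signalling receptor Il6st up 3.25-fold and the chromatin organiser Satb1 down 2.21-fold. T cell receptor activation genes rose in 10 of 23 and fell in 4 (0.116), with Batf at -0.84 ± 0.13. IL-2 and STAT5 targets rose in 8 of 17 and fell in 5 (0.146), and fatty acid oxidation genes rose in 2 of 20 and fell in 4 (0.472). Interferon-stimulated genes rose in 5 of 25 and fell in 6 (0.902), with a median of 0.02 and a mean of -0.13 on opposite sides of 0. The antiviral GTPase Mx1 fell 5.08-fold (log2 fold change -2.35 ± 0.18, adjusted p = 9.56e-07). Adjusted over the list alone, the rises and falls were 6 and 2, 6 and 6, 11 and 5, 8 and 6, 3 and 4, and 7 and 8, in the order given.

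Marker lists of other cell types did not pass camera in CD8 cells. Fry called the B cell (adjusted p = 0.0207), macrophage and monocyte (0.0211) and NK and γδ lists (0.00337) higher. Among dendritic cell markers Itgax (CD11c) fell 3.39-fold (log2 fold change -1.76 ± 0.13, adjusted p = 1.02e-06), Batf3 fell, and Cd86 and Cst3 rose (list adjusted p = 0.589). The Batf3 call (-0.96 ± 0.25) was lost without CD8 control replicate A, CD8 control replicate B or CD8 Foxp3-positive replicate C (adjusted p from 0.0572 to 0.0781). Among B cell markers Ighm (1.16 ± 0.10, adjusted p = 2.05e-06), Cd79b (1.10 ± 0.15, adjusted p = 0.000192) and Cd79a rose and none fell (0.4), the 7 clusters of Ighm giving changes from -0.16 to 1.82. The lysozyme gene Lyz2 rose by 1.82 ± 0.29, C1qb and Apoe rose and Cd68 fell by 0.63 ± 0.15 among macrophage and monocyte markers (0.0796). Of NK and γδ markers 1, Klri2, rose (2.75 ± 0.21, adjusted p = 1.01e-06, list adjusted p = 0.409). Of red cell and platelet markers 1, Pf4, rose, a call lost without CD8 control replicate A, CD8 control replicate C or CD8 Foxp3-positive replicate B (adjusted p from 0.0508 to 0.0595), and the list had a median of -0.06 (0.969). Counts adjusted over the list alone were the same for these 5 lists.

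The second comparison asks the same of CD4 T cells. Itgae rose 29.3-fold from 6.28 ± 0.09 to 11.15 ± 0.17 (log2 fold change 4.87 ± 0.12, adjusted p = 5.18e-11), and Nt5e 38.5-fold from 6.58 ± 0.09 to 11.85 ± 0.03 (log2 fold change 5.27 ± 0.17, adjusted p = 4.17e-10). The type 2 cytokine Il13 fell 109-fold from 12.01 ± 0.11 to 5.24 ± 0.29 (log2 fold change -6.77 ± 0.15, adjusted p = 2.12e-11), and the IL-10 family cytokine Il24 104-fold (log2 fold change -6.71 ± 0.25, adjusted p = 1.59e-09). Epas1, the hypoxia-inducible factor HIF-2α, fell 68.7-fold (log2 fold change -6.10 ± 0.14, adjusted p = 2.51e-11), and Il1r2, the decoy receptor of IL-1, 57.7-fold (log2 fold change -5.85 ± 0.14, adjusted p = 2.51e-11).

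Here 4985 genes passed, 2680 higher and 2305 lower in Foxp3-positive CD4 cells, of which 501 and 610 changed by at least 2-fold. Apol9b (64.1-fold), Hepacam2 (log2 fold change 5.17 ± 0.18), Tph1 (5.15 ± 0.23), Ldlrad4 (4.78 ± 0.13) and Glp1r, the receptor of the gut hormone GLP-1 (4.97 ± 0.20), were among the largest rises. Ly6c2 (-6.47 ± 0.36), Havcr2 (-5.45 ± 0.12) and Tnfrsf8, the activation receptor CD30 (-5.27 ± 0.22), were among the largest falls. Cyp11a1, the first enzyme of steroid hormone synthesis, fell by 5.33 on the log2 scale in its brighter cluster and by 0.97 in its other cluster. The arrays of both groups did not overlap for 37.8% of genes, against 10% by chance. Among named genes that passed, the arrays of Cd8a and Klrk1 overlapped.

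The regulatory T cell signature split in CD4 cells. Of its 28 measured members 13 rose and 11 fell (13 and 11 adjusted over the list alone), and the list did not pass camera (camera adjusted p = 0.321, and adjusted p = 0.642 with an estimated correlation). Fry, which does not compare with other genes, called it higher (adjusted p = 2.28e-05). Il10, an anti-inflammatory cytokine, fell 29-fold (log2 fold change -4.86 ± 0.30, adjusted p = 1.1e-07), Penk 26.4-fold (log2 fold change -4.72 ± 0.15, adjusted p = 4.12e-10) and Ecm1, an extracellular matrix protein, 5.82-fold. TGF-β response genes rose in 15 of 24 cases and fell in 4, Tgfb3, Id2, Junb and Tgfb1 (15 and 4 adjusted over the list alone), with camera adjusted p = 3.15e-05, and adjusted p = 0.0267 with an estimated correlation. Ccr8 did not pass (-0.28 ± 0.14, adjusted p = 0.19), and neither did Tgfbi (-0.04 ± 0.15, adjusted p = 0.899). Retinoic acid response and gut homing genes rose in 7 of 18 cases and fell in 2, Stra6 and Tgm2 (8 and 2 adjusted over the list alone), with camera adjusted p = 0.000747, and adjusted p = 0.251 with an estimated correlation. Dhrs3 rose 14.9-fold (log2 fold change 3.89 ± 0.22, adjusted p = 5.65e-08) and Ccr9 9.75-fold (log2 fold change 3.29 ± 0.18, adjusted p = 3.1e-08), while P2rx7 (-0.23 ± 0.18, adjusted p = 0.405) and Rara (-0.20 ± 0.10, adjusted p = 0.178) did not pass.

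Cytokine, interferon-stimulated and cytotoxic genes fell in Foxp3-positive CD4 cells. Of 17 helper cytokines 10 fell and 3 rose, Lta, Tnf and Ltb (3 and 11 adjusted over the list alone), with camera adjusted p = 8.35e-06, and adjusted p = 0.0298 with an estimated correlation. Il4 fell 21.6-fold (log2 fold change -4.43 ± 0.15, adjusted p = 5.83e-10), Lta rose 5.1-fold (log2 fold change 2.35 ± 0.30, adjusted p = 6.52e-05), and Il17f did not pass (0.24 ± 0.14, adjusted p = 0.272). Of 25 interferon-stimulated genes 22 fell and 1, Gbp3, rose (1 and 22 adjusted over the list alone), by a median of -2.08, with camera adjusted p = 4.56e-22, and adjusted p = 0.0876 with an estimated correlation. Oas2 and Oas3, sensors of viral RNA, fell 18.1-fold and 8.42-fold, and Mx1 14.4-fold (log2 fold change -3.85 ± 0.18, adjusted p = 8.06e-09). Ifit2 did not pass (-0.22 ± 0.14, adjusted p = 0.313), and probes of the Oas and Ifit genes can read near copies, so these genes are uncertain. Of 27 cytotoxic effector genes 19 fell and 4 rose, Tnfsf10, Klrd1, Tnf and Lamp1 (4 and 20 adjusted over the list alone), with camera adjusted p = 2.66e-07, and adjusted p = 0.169 with an estimated correlation. Gzma fell 25.1-fold (log2 fold change -4.65 ± 0.37, adjusted p = 9.96e-07), Gzmb 23.2-fold (log2 fold change -4.54 ± 0.39, adjusted p = 2.13e-06) and Gzmd 27.2-fold, the last pair being uncertain as above, and Gzmm did not pass (0.09 ± 0.17, adjusted p = 0.771).

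Metabolic genes fell in part. In the unfolded protein and amino acid stress list 13 of 19 genes fell and none rose (0 and 14 adjusted over the list alone), with camera adjusted p = 1.72e-07, and adjusted p = 0.216 with an estimated correlation. Asns fell 3.15-fold (log2 fold change -1.66 ± 0.11, adjusted p = 2.52e-07), Slc7a5 2.24-fold and Psat1, of serine synthesis, 1.72-fold, while Herpud1 did not pass (-0.27 ± 0.12, adjusted p = 0.15). Cholesterol synthesis genes fell in 13 of 18 cases and rose in none (0 and 15 adjusted over the list alone), with camera adjusted p = 2.42e-07, and adjusted p = 0.216 with an estimated correlation. Lss and Hsd17b7, enzymes of that pathway, fell by 1.27 ± 0.14 and 1.19 ± 0.15. Glycolysis genes fell in 7 of 18 cases and rose in none (0 and 9 adjusted over the list alone), with camera adjusted p = 0.000509, and adjusted p = 0.555 with an estimated correlation. Slc2a3 fell 3.85-fold (log2 fold change -1.95 ± 0.26, adjusted p = 9.54e-05), the hexokinases Hk2 and Hk1 by 0.82 and 0.73, and Gapdh did not pass (-0.10 ± 0.07, adjusted p = 0.394). IL-2 and STAT5 targets fell in 8 of 17 cases and rose in 2, Lta and Socs2 (2 and 9 adjusted over the list alone), with camera adjusted p = 0.0013, and adjusted p = 0.555 with an estimated correlation. The transcriptional repressor Prdm1 (Blimp-1) fell 4.24-fold (log2 fold change -2.08 ± 0.25, adjusted p = 4.81e-05), and Pim1 did not pass (-0.03 ± 0.11, adjusted p = 0.889).

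CD4 lineage genes fell in 6 of 10 cases and rose in 2, Cxcr5 and Izumo1r (2 and 6 adjusted over the list alone), with camera adjusted p = 0.0161, and adjusted p = 0.169 with an estimated correlation. Naive and memory genes rose in 8 of 14 cases and fell in 3, Satb1, Il7r and Cd28 (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0474, and adjusted p = 0.655 with an estimated correlation. Il6ra, the IL-6 receptor, rose 4.53-fold (log2 fold change 2.18 ± 0.15, adjusted p = 2.26e-07), and Satb1 fell 6.65-fold (log2 fold change -2.73 ± 0.15, adjusted p = 4.04e-08).

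Other lists did not pass in CD4 cells. T cell receptor activation genes rose in 8 of 23 cases and fell in 7 (camera adjusted p = 0.412), the nuclear receptors Nr4a3 and Nr4a1 rising 6.61-fold and 3.7-fold, Batf falling 6.01-fold and Irf4 not passing (0.17 ± 0.14, adjusted p = 0.453). Chemokine receptors and integrins rose in 8 of 25 and fell in 7 (0.643), with Ccr1 down 15.1-fold. Inhibitory receptor genes rose in 5 of 19, Tox, Nr4a3, Nr4a1, Cd160 and Pdcd1, and fell in 5, Havcr2, Pdcd1lg2, Cd274, Entpd1 and Vsir (0.94). Helper lineage factors rose in 5 of 15 and fell in 5 (0.959), with a median of 0.17 and a mean of -0.10 on opposite sides of 0. Il12rb2 fell 30-fold in that list. Cell cycle genes rose in 6 of 29 and fell in 1, E2f1 (0.244). Fatty acid oxidation genes rose in 5 of 20 and fell in 1, Acadl, at -1.38 ± 0.12 (0.342). CD8 lineage genes rose in 4 of 10, Itgae, Xcl1, Klrd1 and Cd8a, and fell in 4, Eomes, Cd8b1, Klrk1 and Runx3 (0.601). Adjusted over the list alone, the rises and falls were 11 and 7, 10 and 7, 5 and 5, 6 and 5, 8 and 1, 6 and 1, and 5 and 4, in the order given. The Klrk1 fall (-1.05 ± 0.31, adjusted p = 0.0248) lost its call without CD4 control replicate A, CD4 control replicate B, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate B (adjusted p from 0.0568 to 0.105).

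Of the marker lists, none passed camera in CD4 cells, while fry called the B cell (adjusted p = 0.00378) and NK and γδ lists (0.00145) higher and the macrophage and monocyte list (0.0172) lower. Among dendritic cell markers Batf3 (-1.57 ± 0.25, adjusted p = 0.000523), Fcer1g and H2-Ab1 fell and Ccl17 rose (list adjusted p = 0.601), the Fcer1g call being lost without CD4 control replicate A, CD4 control replicate B, CD4 Foxp3-positive replicate A, CD4 Foxp3-positive replicate B or CD4 Foxp3-positive replicate C (adjusted p from 0.063 to 0.154, log2 fold change -0.90 without CD4 control replicate B against -1.38). Among B cell markers Ighm (1.82 ± 0.10, adjusted p = 2.8e-08) and Cd79b (0.77 ± 0.15, adjusted p = 0.00241) rose and Ebf1 and Cd22 fell (0.502), the Ebf1 call being lost without CD4 control replicate A, CD4 control replicate C, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate C (adjusted p from 0.0503 to 0.0795). Fcgr3, an Fc receptor, fell 4.75-fold, Cd68 fell by 1.19 and Lyz2 rose among macrophage and monocyte markers (0.388), the Lyz2 call being lost without CD4 control replicate A or CD4 Foxp3-positive replicate A (adjusted p from 0.068 to 0.0704). Klri2 (2.58 ± 0.21, adjusted p = 1.29e-06) and Il23r rose among NK and γδ markers (0.373), the Il23r call being lost without CD4 control replicate B, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate B (adjusted p from 0.0586 to 0.072). The red cell and platelet list did not pass (0.959). Counts adjusted over the list alone were the same for these 5 lists.

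The effects in CD8 and CD4 cells shared no arrays and overlapped in many genes. Itgae, Ldlrad4, Ccr9, Xcl1 and Nt5e rose in both, and Ly6c2, Havcr2, Il12rb2, Ccr2 and Asns fell in both. In total 1143 genes rose in both cell types, where independent lists of these sizes would share 252, and 815 fell in both, against 244. Opposite calls were fewer than independent lists would give: 154 genes rose in CD8 and fell in CD4 cells, against 216, and 156 did the reverse, against 284. Across all genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.554 and Spearman rho = 0.302.

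**Figure D3:**
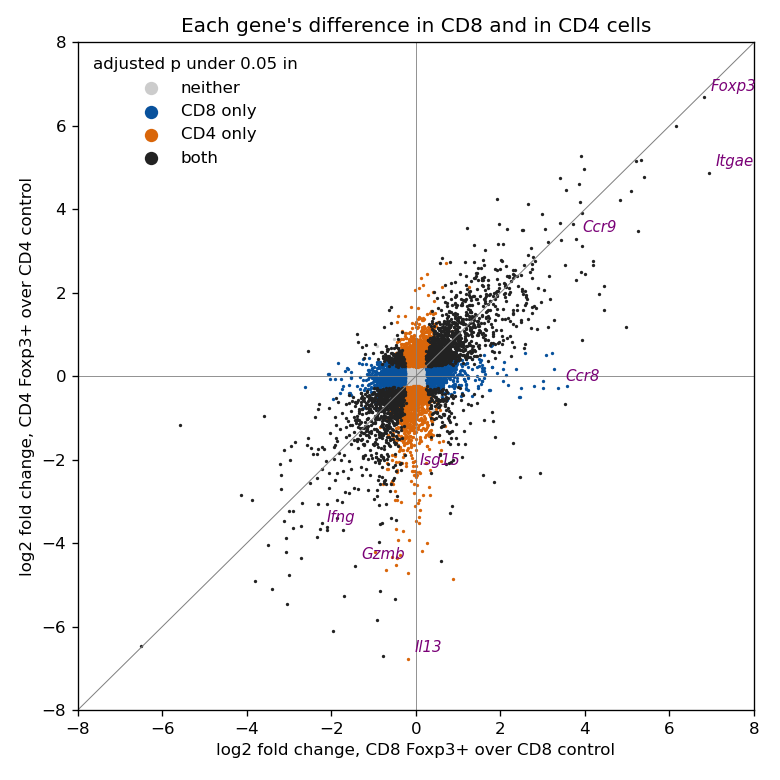
Log2 fold change of each of 22180 genes in CD8 cells (horizontal) and CD4 cells (vertical), Foxp3-positive over control, coloured by the cell types in which the adjusted p was under 0.05. Foxp3, Itgae and Ccr9 lie high in both directions, while Il13 has -0.18 in CD8 cells and -6.77 in CD4 cells.

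A test of the interaction found 2993 genes whose change differed between CD8 cells after 4 days and CD4 cells after 5 days, 1334 with a higher and 1659 with a lower change in CD8 than in CD4 cells. Tgfb3 rose 7.66-fold in CD8 cells and fell 5.02-fold in CD4 cells (difference 5.26 ± 0.34, adjusted p = 1.27e-06). The type 2 cytokine genes Il13 (difference 6.59 ± 0.21, adjusted p = 2.57e-09) and Il4 (difference 5.02 ± 0.21, adjusted p = 4.56e-08) and Il10 (difference 5.72 ± 0.42, adjusted p = 3.61e-06) fell in CD4 cells, where the control means were 12.01, 8.94 and 10.34, and had means of 5.53, 4.43 and 5.92 in CD8 controls. Ccr8 rose in CD8 cells to a level below that of both CD4 groups, from 4.08 to 7.45 against 9.82 and 9.54 (difference 3.66 ± 0.20, adjusted p = 3.79e-07). Cmah, an enzyme of sialic acid hydroxylation, fell in CD8 cells from 10.14 to 7.58 and rose from 7.72 to 8.33 in CD4 cells, a call lost without CD4 control replicate A, CD4 control replicate B, CD4 control replicate C, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate C (adjusted p from 0.0521 to 0.126) (difference -3.17 ± 0.27, adjusted p = 1.12e-05). Il18r1, of the IL-18 receptor, fell in CD8 and rose in CD4 cells (difference -2.43 ± 0.23, adjusted p = 2.4e-05). The sialyltransferase St8sia6 rose more in CD4 cells (difference -2.36 ± 0.28, adjusted p = 0.000139), as did the membrane-bending protein gene Fnbp1l (difference -2.32 ± 0.17, adjusted p = 3.32e-06).

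Of 24 lists 14 differed between the cell types with the preset correlation and 5 with an estimated one. Interferon-stimulated genes had 22 higher and 0 lower of 25 (23 and 0 adjusted over the list alone), camera adjusted p = 5.41e-26, and adjusted p = 0.0346 with an estimated correlation. Helper cytokines had 9 higher and 1 lower of 17 (10 and 2 adjusted over the list alone), camera adjusted p = 9.81e-08, and adjusted p = 0.00722 with an estimated correlation. The regulatory signature had 18 higher and 3 lower of 28 (18 and 4 adjusted over the list alone), camera adjusted p = 2.92e-11, and adjusted p = 0.00722 with an estimated correlation. The TGF-β response had 12 higher and 2 lower of 24 (12 and 4 adjusted over the list alone), camera adjusted p = 5.38e-05, and adjusted p = 0.00824 with an estimated correlation. CD4 lineage genes had 6 higher and 0 lower of 10 (7 and 0 adjusted over the list alone), camera adjusted p = 4.65e-07, and adjusted p = 0.00722 with an estimated correlation. The lower members were Ikzf2, Nrp1 and Nt5e in the regulatory signature, Tgif1 and Smad3 in the TGF-β response, and Ltb among the cytokines.

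The other list differences were lost with an estimated correlation. Cell cycle genes had 0 higher and 20 lower of 29 (0 and 25 adjusted over the list alone), camera adjusted p = 5.46e-15, and adjusted p = 0.202 with an estimated correlation. IL-2 and STAT5 targets had 8 higher and 0 lower of 17 (9 and 0 adjusted over the list alone), camera adjusted p = 6.53e-06, and adjusted p = 0.273 with an estimated correlation. Cytotoxic effector genes had 9 higher and 2 lower of 27 (9 and 2 adjusted over the list alone), camera adjusted p = 0.00437, and adjusted p = 0.359 with an estimated correlation, the lower members being Gzmk and Serpinb9. Inhibitory receptors had 8 higher and 4 lower of 19 (8 and 4 adjusted over the list alone), camera adjusted p = 0.0155, and adjusted p = 0.273 with an estimated correlation. Chemokine receptors and integrins had 7 higher and 5 lower of 25 (10 and 6 adjusted over the list alone), camera adjusted p = 0.0215, and adjusted p = 0.273 with an estimated correlation. Helper lineage factors had 5 higher and 2 lower of 15 (6 and 2 adjusted over the list alone), camera adjusted p = 0.0302, and adjusted p = 0.202 with an estimated correlation, the largest being Maf (difference 4.19 ± 0.22, adjusted p = 1.95e-07). Naive and memory genes had 3 higher and 5 lower of 14 (3 and 8 adjusted over the list alone), camera adjusted p = 0.0491, and adjusted p = 0.606 with an estimated correlation. Cholesterol synthesis genes had 0 higher and 3 lower of 18 (0 and 4 adjusted over the list alone), camera adjusted p = 0.0302, and adjusted p = 0.606 with an estimated correlation, the members being Hmgcs1, Cyp51 and Sc5d. Macrophage and monocyte markers had 1 higher and 0 lower of 14 (1 and 0 adjusted over the list alone), camera adjusted p = 0.00892, and adjusted p = 0.202 with an estimated correlation, the member being Fcgr3. The retinoic acid list (median -0.06, mean 0.34, camera adjusted p = 0.601) and the T cell receptor activation list (median -0.04, mean 0.05, 0.601) did not pass and had medians and means of opposite sign.

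**Figure D4:**
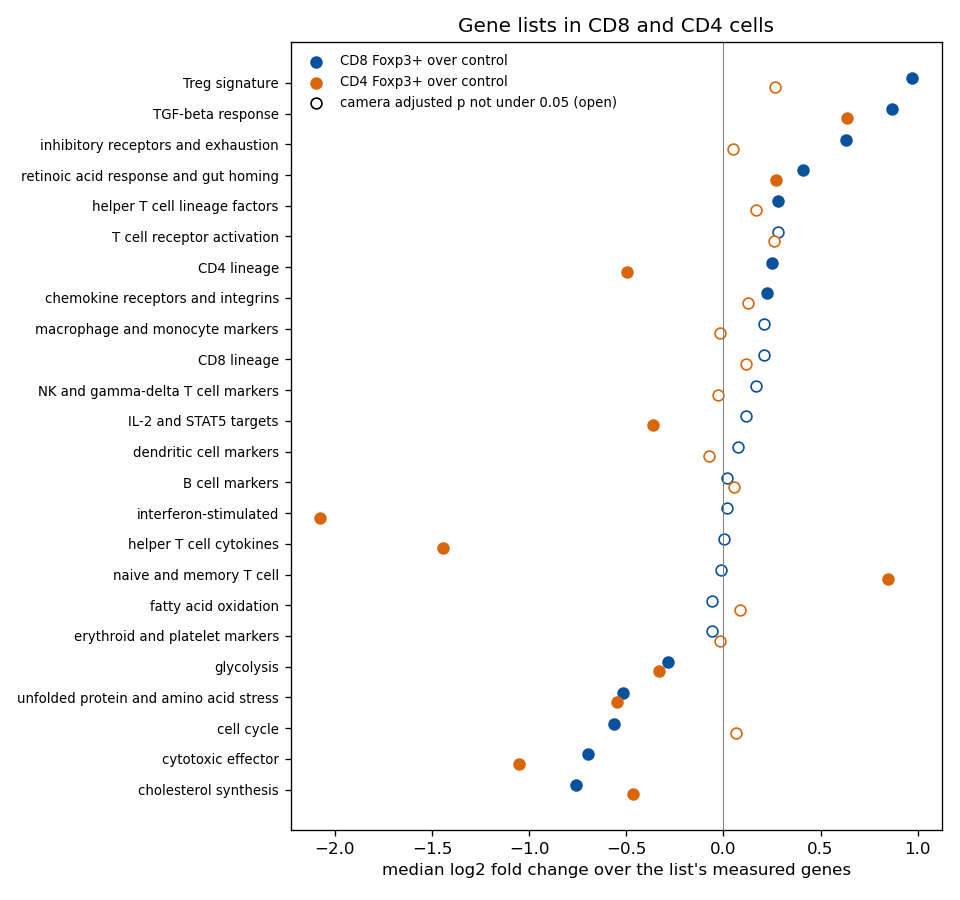
Median log2 fold change over the measured genes of each of 24 fixed gene lists in CD8 and CD4 cells, Foxp3-positive over control, filled where camera's adjusted p was under 0.05. The cell cycle median is -0.56 in CD8 and 0.06 in CD4 cells, and the interferon-stimulated median is 0.02 and -2.08.

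The next comparison sets Foxp3-positive CD8 cells against Foxp3-positive CD4 cells, which also differed by 1 day of culture. Foxp3 itself did not differ (0.04 ± 0.23, adjusted p = 0.964). Besides Cd8a, Cd8b1 and Cd4, the activating receptor Klrk1 (NKG2D) was 17.6-fold higher in the CD8 cells (log2 fold change 4.14 ± 0.31, adjusted p = 6.86e-06), and Gzmb 8.36-fold higher (log2 fold change 3.06 ± 0.39, adjusted p = 0.00052). Klra5, an NK receptor gene with near copies and therefore uncertain, was 8.13-fold higher (log2 fold change 3.02 ± 0.21, adjusted p = 5.04e-06), and the phospholipid flippase Atp8b4 8-fold higher (log2 fold change 3.00 ± 0.12, adjusted p = 4.02e-08). Akr1c18, which inactivates progesterone, was 24.9-fold lower in the CD8 cells (log2 fold change -4.64 ± 0.26, adjusted p = 6.49e-07), the mucin Muc13 14.3-fold lower (log2 fold change -3.84 ± 0.18, adjusted p = 1.13e-07), and Cd40lg, the helper signal CD40 ligand, 6.7-fold lower (log2 fold change -2.74 ± 0.13, adjusted p = 1.13e-07).

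Limma called 1044 genes, 534 higher and 510 lower in CD8 cells, 129 and 95 of them by at least 2-fold. The count moved to 674 without CD8 Foxp3-positive B and to 687 without CD4 Foxp3-positive A. Of all genes 22.7% had arrays that did not overlap, against 10% by chance. St8sia6 (-2.68 ± 0.20), Il6ra (-2.63 ± 0.15) and Fnbp1l (-2.29 ± 0.12) were lower in the CD8 cells.

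CD8 lineage genes had 8 of 10 members higher and 0 lower in CD8 cells (8 and 0 adjusted over the list alone), with camera adjusted p = 5.75e-20, and adjusted p = 0.0486 with an estimated correlation. Xcl1 was 4.23-fold higher and Crtam, an adhesion receptor of cytotoxic cells, 3.45-fold higher. Cytotoxic effector genes had 10 higher and 1 lower of 27 (13 and 1 adjusted over the list alone), camera adjusted p = 3.16e-09, and adjusted p = 0.115 with an estimated correlation, the lower member being Tnfsf10. Naive and memory genes had 0 higher and 7 lower of 14 (0 and 7 adjusted over the list alone), camera adjusted p = 2.44e-06, and adjusted p = 0.287 with an estimated correlation. T cell receptor activation genes had 2 higher and 9 lower of 23 (3 and 10 adjusted over the list alone), camera adjusted p = 5.8e-06, and adjusted p = 0.0553 with an estimated correlation, the higher members being Cd69 and Nr4a2. CD4 lineage genes had 1 higher and 5 lower of 10 (3 and 5 adjusted over the list alone), camera adjusted p = 0.000498, and adjusted p = 0.0553 with an estimated correlation, Cxcr5 being higher and Cd4, Cd40lg, Tnfrsf4, Izumo1r and Zbtb7b lower. Retinoic acid genes had 1 higher and 4 lower of 18 (2 and 7 adjusted over the list alone), camera adjusted p = 0.00226, and adjusted p = 0.343 with an estimated correlation, Ccr9 being higher and Gpr15, Stra6, Cyp26b1 and Crabp2 lower. Inhibitory receptors had 6 higher and 4 lower of 19 (8 and 5 adjusted over the list alone), camera adjusted p = 0.0429, and adjusted p = 0.431 with an estimated correlation, with Havcr2 3.58-fold higher and Cd5, Nr4a1, Nr4a3 and Pdcd1 lower. Macrophage and monocyte markers had 1 higher and 0 lower of 14 (5 and 0 adjusted over the list alone), camera adjusted p = 0.0181, and adjusted p = 0.316 with an estimated correlation, the member being Fcgr3.

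The regulatory signature did not pass as a list (camera adjusted p = 0.336, and adjusted p = 0.66 with an estimated correlation), with 4 members higher in CD8 cells, Fgl2, Il10, Tigit and Itgae, and 7 lower, among them Ecm1 (-2.30 ± 0.14, adjusted p = 1.96e-06). The TGF-β response had 3 higher, Tgfb3, Itgae and Smurf2, and 4 lower, Ccr8, Sox4, Smad3 and Itgb8 (camera adjusted p = 0.465). The cell cycle list did not pass here (camera adjusted p = 0.0568, and adjusted p = 0.893 with an estimated correlation), with a median of -0.07. Of 25 interferon-stimulated genes 1, Oas3, was higher and 1, Ifih1, lower (0.133). The IL-2 and STAT5 list had a median of -0.11 and a mean of 0.10 (0.574).

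The last comparison gives the baseline, CD8 against CD4 controls, with the same difference in culture time. Ecm1 was 102-fold lower in the CD8 controls (log2 fold change -6.68 ± 0.14, adjusted p = 2.25e-11), Akr1c18 98.3-fold (log2 fold change -6.62 ± 0.26, adjusted p = 3.34e-09) and Penk 94.6-fold (log2 fold change -6.56 ± 0.15, adjusted p = 2.71e-11). Il13 was at 5.53 ± 0.22 in CD8 and 12.01 ± 0.11 in CD4 controls, a 89.3-fold difference (log2 fold change -6.48 ± 0.15, adjusted p = 2.71e-11). Klrk1 was 9.14-fold higher in CD8 controls (log2 fold change 3.19 ± 0.31, adjusted p = 1.07e-05), Il18r1 8.31-fold (log2 fold change 3.06 ± 0.16, adjusted p = 5.97e-08), Klrd1 6.9-fold (log2 fold change 2.79 ± 0.20, adjusted p = 7.11e-07) and Nt5dc2, a gene of the nucleotidase family, 6.58-fold (log2 fold change 2.72 ± 0.13, adjusted p = 1.69e-08). Cyp11a1 was lower by -6.07 ± 0.11 in its brighter cluster.

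Here 4636 genes passed, 2692 higher and 1944 lower in CD8 controls, but the lower ones held more of the changes of at least 2-fold, 460 against 192. Arrays did not overlap for 33.7% of genes, against 10% by chance. Among named genes that passed, the arrays of Il6st overlapped. Across genes, which are not independent replicates, the CD8 minus CD4 differences of controls and Foxp3-positive cells correlated at Pearson r = 0.185 and Spearman rho = 0.046. Of the genes called in controls 368 were called with the same sign in Foxp3-positive cells and 158 with the opposite sign.

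Interferon-stimulated genes had 0 of 25 members higher and 22 lower in CD8 cells (0 and 22 adjusted over the list alone), with camera adjusted p = 2.93e-25, and adjusted p = 0.0373 with an estimated correlation. Helper cytokines had 0 higher and 11 lower of 17 (0 and 11 adjusted over the list alone), camera adjusted p = 6.55e-10, and adjusted p = 0.00236 with an estimated correlation. The regulatory signature had 2 higher and 19 lower of 28 (3 and 20 adjusted over the list alone), camera adjusted p = 8.94e-14, and adjusted p = 0.00236 with an estimated correlation, the higher members being Ikzf2 and Nt5e. The TGF-β response had 1 higher and 13 lower of 24 (2 and 14 adjusted over the list alone), camera adjusted p = 4.12e-07, and adjusted p = 0.00236 with an estimated correlation, the higher member being Tgif1. CD4 lineage genes had 1 higher and 8 lower of 10 (1 and 8 adjusted over the list alone), camera adjusted p = 4.37e-11, and adjusted p = 0.00236 with an estimated correlation, the higher member being Cxcr5. Cell cycle genes had 24 higher and 0 lower of 29 (27 and 0 adjusted over the list alone), camera adjusted p = 1.34e-14, and adjusted p = 0.172 with an estimated correlation, the ribonucleotide reductase gene Rrm2 being higher by 0.60 ± 0.13.

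CD8 lineage genes had 8 higher and 1 lower of 10 (8 and 1 adjusted over the list alone), camera adjusted p = 8.93e-08, and adjusted p = 0.101 with an estimated correlation, the lower member being Itgae. IL-2 and STAT5 targets had 0 higher and 9 lower of 17 (0 and 9 adjusted over the list alone), camera adjusted p = 4.12e-07, and adjusted p = 0.231 with an estimated correlation. Helper lineage factors had 3 higher and 7 lower of 15 (3 and 7 adjusted over the list alone), camera adjusted p = 0.00645, and adjusted p = 0.101 with an estimated correlation, with Maf lower (-4.90 ± 0.15, adjusted p = 4.8e-10) and Il18r1, Cxcr5 and Tbx21 higher. Cholesterol synthesis genes had 7 higher and 1 lower of 18 (11 and 1 adjusted over the list alone), camera adjusted p = 0.00211, and adjusted p = 0.369 with an estimated correlation, Hsd17b7 being lower. Fatty acid oxidation genes had 5 higher and 1 lower of 20 (11 and 2 adjusted over the list alone), camera adjusted p = 0.0263, and adjusted p = 0.369 with an estimated correlation, with Acadl lower and Echs1, Eci1, Etfdh, Etfa and Hadhb higher. Chemokine receptors and integrins had 5 higher and 9 lower of 25 (5 and 9 adjusted over the list alone), camera adjusted p = 0.0263, and adjusted p = 0.279 with an estimated correlation, with Ccr8 lower (-5.74 ± 0.14, adjusted p = 4.78e-11). T cell receptor activation genes had 4 higher and 9 lower of 23 (5 and 10 adjusted over the list alone), camera adjusted p = 0.0209, and adjusted p = 0.231 with an estimated correlation, with Nr4a3, Nr4a2, Myc and Dusp2 higher. Retinoic acid genes had 1 higher and 6 lower of 18 (1 and 6 adjusted over the list alone), camera adjusted p = 0.0152, and adjusted p = 0.367 with an estimated correlation, with a median of 0.00 and a mean of -0.65, P2rx7 being 12.2-fold lower and Itga4 higher. The unfolded protein list did not pass (0.978), its median of 0.03 and camera's direction having opposite signs.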

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

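Below, tests of spread, single arrays, dendritic cells, saturation (also of Il2ra alone) and Foxp3-expressing controls were chosen only after seeing the result they explain. Those using lists written after the first results were not fixed beforehand either. Results are listed because their change with treatment and Foxp3 sort differed between CD8 and CD4 cells by limma's interaction test, or they lie outside the genes compared. The interaction also sets 4 days of culture (CD8) against 5 (CD4). The interaction passed for 2993 genes (13.5%), 63 of the 119 named genes and, by camera, 14 of 24 lists. Named genes were partly picked by large changes, also of the interaction, which favours their share. Only 1 of 100 drawn splits of the arrays (200 are possible), the real one, gave as many genes. Splits that mix treated and control arrays widen the spread within groups by construction, so these counts do not exclude chance. Besides the real one, the 19 drawn splits that keep the true groups in 1 cell type reached up to 1899 genes, and the rest 0. Exchanging control and Foxp3-positive labels in CD8 cells, a split not among those drawn, gave 5770 genes, since by construction it adds the effects instead of subtracting them. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real and the highest other counts were 4430 and 1 in CD8 cells, 4985 and 0 in CD4 cells, 1044 and 0 between the Foxp3-positive groups and 4636 and 0 between the controls.

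Lists with a higher change in CD8 than in CD4 cells had these median differences on the log2 scale: interferon-stimulated 1.79, helper cytokines 1.29, CD4 lineage 1.12, regulatory signature 0.87, cytotoxic effector 0.61, IL-2 and STAT5 targets 0.44, chemokine receptors and integrins 0.41, TGF-β response 0.38, macrophage and monocyte markers 0.34, inhibitory receptors 0.33 and helper lineage factors 0.28. Cholesterol synthesis (-0.25), naive and memory (-0.41) and cell cycle genes (-0.63) had a lower change in CD8 cells.

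Among named genes the difference on the log2 scale, CD8 minus CD4, was above 4 for Il13 6.59, Il24 5.94, Il10 5.72, Tgfb3 5.26, Il4 5.02, Il1r2 4.93, Cyp11a1 4.83, Penk 4.54, Ecm1 4.38, Oas2 4.34, Maf 4.19 and Epas1 4.14. Further T cell function genes with a higher change in CD8 cells were Gzma 3.95, Gzmb 3.10, Ccr8 3.66, Ccr1 3.49, Tnfrsf8 3.56, Klra5 3.07, Havcr2 2.41, Itgae 2.05, Cd40lg 1.33, Cd8b1 1.66 and Izumo1r 1.17. Transcription factors and signalling genes were Ahr 2.56, Batf 1.75, Satb1 1.59, Prdm1 1.40, Ldlrad4 0.62 and Rara 0.48. Interferon-stimulated and other genes were Oas3 2.19, Mx1 1.51, P2rx7 3.81, Fcgr3 2.59, Akr1c18 1.98, Igh-VS107 1.79, Adam8 1.69, Atp8b4 1.13, Acadl 0.82 and Hk1 0.62. Genes with a lower change in CD8 cells included the surface genes Il18r1 -2.43, Il6ra -2.00, Nt5e -1.35, Sema4a -1.29, Itgax -1.69, Muc13 -1.76, Glp1r -0.99 and Ighm -0.66 and the regulators Nr4a3 -2.16, Nr4a1 -1.26 and Tox -1.12. Enzymes and other genes with a lower change were Cmah -3.17, Galnt3 -2.63, Gzmk -2.37, St8sia6 -2.36, Fnbp1l -2.32, Nt5dc2 -1.86, Anxa2 -1.11, Echs1 -1.07, Hmgcs1 -0.99, Eci1 -0.97, Asns -0.91, Rrm2 -0.67 and Cdt1 -0.63.

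The differences of 7 of these genes lost their call with single arrays left out: Anxa2 without CD8 control replicate A, CD8 control replicate B, CD8 control replicate C, CD8 Foxp3-positive replicate B, CD8 Foxp3-positive replicate C, CD4 control replicate A, CD4 control replicate B, CD4 control replicate C or CD4 Foxp3-positive replicate A (adjusted p from 0.0507 to 0.0929), Glp1r without CD8 control replicate A, CD8 control replicate C, CD8 Foxp3-positive replicate A, CD8 Foxp3-positive replicate C, CD4 control replicate A, CD4 control replicate B, CD4 control replicate C, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate B (adjusted p from 0.0537 to 0.0836), Hk1 without CD8 control replicate B, CD8 control replicate C, CD8 Foxp3-positive replicate A, CD8 Foxp3-positive replicate B, CD4 control replicate A, CD4 control replicate B, CD4 control replicate C, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate B (adjusted p from 0.0543 to 0.0757) and Ldlrad4 without CD8 control replicate A, CD8 control replicate B, CD8 Foxp3-positive replicate A, CD8 Foxp3-positive replicate B, CD8 Foxp3-positive replicate C, CD4 control replicate A, CD4 control replicate B, CD4 control replicate C, CD4 Foxp3-positive replicate A or CD4 Foxp3-positive replicate C (adjusted p from 0.0532 to 0.089). The same held for Prdm1 without CD8 control replicate B, CD8 Foxp3-positive replicate A, CD8 Foxp3-positive replicate C or CD4 control replicate C (adjusted p from 0.0513 to 0.0531). Rara lost its call with any single array left out except CD8 control A, CD4 control A and CD4 Foxp3-positive C (adjusted p from 0.0553 to 0.0805). Rrm2 lost its call with any single array left out except CD8 control C, CD8 Foxp3-positive B, CD4 control A and CD4 Foxp3-positive C (adjusted p from 0.0567 to 0.067).

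Clusters outside the compared genes also changed. Of 9030 clusters with no listed symbol 404 passed in CD8 and 656 in CD4 cells, and of 1814 with several symbols 198 and 208.

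The first pattern weighed is that fewer genes differed between CD8 and CD4 cells in the Foxp3-positive samples (1044) than in the controls (4636). A larger spread among Foxp3-positive arrays could not by itself lower their count against that of the controls. The model pooled the spread of a gene over the 4 groups, so both comparisons had the same standard error. Median SDs were 0.12 and 0.126 in CD8 and CD4 Foxp3-positive arrays and 0.135 and 0.125 in their controls. The noise-corrected size of the differences also argues against it, 0.233 against 0.413. Their ratio of 0.564 stayed between 0.542 and 0.603 with any 1 array left out. A single array is argued against by the ratio of the counts, which was at least 3.77 with any 1 array left out. Without the interferon-stimulated and type 2 lists the ratio was 0.587, so the difference remained in the other genes. So few genes can hardly move the ratio whatever the source. The test therefore cannot decide on a CD4 control program, and one wider than these lists stays open. A convergence of CD8 and CD4 cells under TGF-β and retinoic acid, or among cells selected for Foxp3, may explain the pattern, and the design cannot separate these.

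The second pattern is that interferon-stimulated genes were higher in CD4 controls than in the other groups. Dendritic cells left in those samples stay open, as several abundant dendritic cell genes lay near or below 5.60 throughout. The genes' larger median difference was 0.06 with 0 past in both comparisons. H2-Ab1 (1.05), Ccl22 (1.57) and Ccl17 (-0.78) passed limma in 1 each. Removal of dendritic cells by the sort was not measured. A single CD4 control array is argued against by the list's array means, the lowest CD4 control lying 1.35 above the highest of the other 9. Interferon-γ made by the CD4 control cells may contribute: Ifng differed by -1.5 between CD8 and CD4 controls, and 15 of 20 of its targets were higher in CD4 controls. With it, Ifng fell by 3.66 in CD4 cells while 10 targets fell and 2 rose, and against it as the whole source, Ifng fell by 2.26 in CD8 cells while 8 targets rose and 1 fell. The targets were not shown to answer interferon-γ alone, so their counts cannot tell it from other interferons.

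The third pattern is that the regulatory signature passed camera in CD8 and not in CD4 cells (interaction camera adjusted p = 2.92e-11, and adjusted p = 0.00722 with an estimated correlation), although fry called it higher in CD4 cells too (adjusted p = 2.28e-05). Saturation of the arrays is argued against by 11 members that fell in CD4 cells from control means of 12.69 (Ecm1) or lower, but cannot be told for Il2ra, whose CD4 control mean lay 0.97 below the highest gene value. Foxp3-expressing cells among the CD4 controls, which the GFP-negative sort would remove, are argued against by Foxp3 at 5.76 there and 12.44 in CD4 Foxp3-positive cells; it differed by -0.1 between CD8 and CD4 controls, and by -0.44 without CD8 control replicate C (adjusted p = 0.0466, and 0.481 to 0.975 under the other alternatives). Of the 11 members that fell in CD4 cells 10 were higher in CD4 than in CD8 controls, and 11 members rose in both cell types. The count of 10 is favoured by construction, since both comparisons use the same CD4 control arrays. A candidate explanation is that stimulated CD4 controls already express part of this signature without Foxp3, with 19 members higher in CD4 and 2 in CD8 controls, and this hypothesis was found and examined on the same data.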

How the results depend on the processing

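All alternatives were fixed before the data were examined. In the order CD8 cells, CD4 cells, interaction, Foxp3-positive cells, controls and genes shared by CD8 and CD4 cells, an adjusted p under 0.01 left 2914, 3219, 1456, 529, 2920 and 1279 genes, and a change of at least 2-fold 803, 1111, 799, 224, 652 and 434, by construction fewer. Camera with an estimated correlation called 2, 2, 5, 1 and 5 lists in place of 12, 11, 14, 8 and 14. The correlation of the CD8 and CD4 effects was 0.59 with the lowest 33.3% of genes by mean level left out, against 0.554, and the cause was not tested.

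Leaving out 1 array at a time gave 3472 to 4547, 3834 to 5259, 2253 to 3158, 674 to 1145, 3588 to 4573 and 1655 to 1986 genes, a correlation of 0.539 to 0.562, and 9 to 13, 10 to 11, 11 to 14, 6 to 10 and 12 to 14 lists. The count for Foxp3-positive cells moved by over 1.5 times without CD8 Foxp3-positive replicate B (674) and without CD4 Foxp3-positive replicate A (687).

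The replicate letter as a block gave 4359, 4872, 2921, 989, 4595 and 1916 genes, but the letters showed no consistent pairing of the arrays. Same-letter correlations of residuals ran from -0.102 to 0.137, with a median of 0.034 against -0.006 for other letters. For replicates A, B and C they were 0.054, 0.135 and 0.137 between the CD8 groups and 0.012, -0.102 and -0.039 between the CD4 groups. Centring on the median moved the share of called genes that were higher from 53.8 to 61.6% in CD4 cells, 44.6 to 37.6% for the interaction and 58.1 to 65.1% in controls. A model of only the groups compared gives no value for the interaction or the correlation. Of 7529 alternative values for 383 named gene results 7293 stayed on the same side of the threshold with the same sign, 128 lost and 106 gained a call and 2 reversed. With the mean over the clusters of a gene Cyp11a1 in CD8 cells was 0.12 and the Ighm interaction 0.34, since their clusters differ in direction. In 23 named results the call was lost under at least 1 alternative, among them Hmgcs1 in CD4 cells without CD4 Foxp3-positive replicate B (adjusted p = 0.0525), Nr4a1 in CD8 cells without CD8 control replicate B or CD8 Foxp3-positive replicate C (adjusted p from 0.08 to 0.101, log2 fold change 0.40 without CD8 Foxp3-positive replicate C against 0.63) and Nr4a3 in CD8 cells without CD8 control replicate A or CD8 Foxp3-positive replicate C (adjusted p from 0.0609 to 0.0686). Scanner-level background was not analysed here, so signal over background could not be set against these results.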

Other observations

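The type 2 helper list and the 28 gene families below were chosen only after the first results were seen. Type 2 cytokine genes stood high in the CD4 controls, but the list does not test a type 2 helper program in the CD4 control cells, since it was written for the pattern and most of its members stood in lists examined before. Of its members outside the named genes 7 of 7 were higher in CD4 than in CD8 controls, namely Il5, Il9, Gata3, Il17rb, Ccr4, Pparg and Il4ra. The transcription factor Gata3 was at 10.76 in CD4 and 8.79 in CD8 controls, and Il5 at 8.55 and 4.96. With treatment and Foxp3 sort Gata3 and Il5 fell in CD4 cells by 1.22 and 3.48, whereas Il17rb rose by 2.41.

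Families of related genes were tested with limma's camera. Interleukin genes were the only family of 28 whose calls held with an estimated correlation. They had 0 higher and 11 lower of 33, adjusted p = 6e-05, and 0.0453 with an estimated correlation in CD4 cells, Foxp3-positive against control. The interaction gave 9 higher and 0 lower of 33, adjusted p = 9.23e-07, and 0.019 with an estimated correlation, and the controls, CD8 against CD4, 0 higher and 11 lower of 33, adjusted p = 3.7e-07, and 0.0166 with an estimated correlation. The helper cytokine list, already called in the same comparisons, holds interleukin genes such as Il4, Il10 and Il13. The interleukin calls are therefore no separate support for that result. The calls of the families below were lost with an estimated correlation. In controls, CD8 against CD4, mitochondrial ribosomal proteins had 41 higher and 1 lower of 71, adjusted p = 2.24e-13, and 0.224 with an estimated correlation, and complex I genes had 21 higher and 0 lower of 42, adjusted p = 2.15e-07, and 0.142 with an estimated correlation. The TRiC chaperonin genes had 7 higher and 0 lower of 9, adjusted p = 0.000228, and 0.202 with an estimated correlation. The tRNA synthetases in CD8 cells, Foxp3-positive against control, had 1 higher and 10 lower of 14, adjusted p = 2.47e-05, and 0.36 with an estimated correlation. Guanylate-binding proteins, antimicrobial GTPases, had 4 higher and 0 lower of 10, adjusted p = 0.00501, and 0.527 with an estimated correlation in CD8 cells and 3 higher and 7 lower of 10, adjusted p = 0.0135, and 0.484 with an estimated correlation in CD4 cells, and the interaction gave 7 higher and 0 lower of 10, adjusted p = 1.85e-07, and 0.238 with an estimated correlation. Immunity-related GTPases in CD8 cells had 5 higher and 0 lower of 5, adjusted p = 2.47e-05, and 0.205 with an estimated correlation, and Schlafen genes in CD4 cells 0 higher and 6 lower of 9, adjusted p = 6e-05, and 0.0764 with an estimated correlation. Killer lectin-like receptors, uncertain for their near copies, had 7 higher and 0 lower of 23, adjusted p = 2.37e-09, and 0.093 with an estimated correlation in Foxp3-positive CD8 against CD4 cells.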
